A study of Mus musculus with 9 samples.

How the data were processed

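RNA was sequenced from 9 libraries of Dmdmdx mouse embryonic fibroblasts (MEFs): 3 of MEFs, 3 of MEFs with MyoD and 3 of MEFs with MyoD and F/R/C. RNA was extracted with RNeasy and libraries of polyadenylated RNA were made with the TruSeq Stranded mRNA kit, per the labels. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.19, trimmed with Trimmomatic 0.36 and assigned to transcripts with kallisto 0.44 on GRCm38.p6, and edgeR 3.28 was used by the authors; the annotation release, the kallisto options and the use of strand were not given in the sources used here. The deposited tables hold, per the file headers, an estimated count (expected count) and a TPM value, scaled for effective transcript length, for each of 121843 transcripts in each library. The deposited TPM values were used for levels of single transcripts and of Dmd summed over its transcripts, and the deposited estimated counts for everything else.

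Transcripts were joined to genes by Ensembl identifier with the GENCODE M21 annotation of GRCm38, which held 121104 of them; the other 739 took 0.200% to 0.494% of the counts of a library and were left out of the gene totals. Estimated counts were summed over the transcripts of a gene and rounded to whole counts, which gave 35675 genes. The totals per library were 21112071 to 24291056, and 14002 to 15379 genes had at least 10 counts. Levels are given as CPM, counts scaled to equal effective library sizes (the library's total times its TMM factor), as mean ± SD over 3 libraries. Log2 fold changes are given ± SE, taken as the absolute log2 fold change divided by the square root of the test's F statistic. This SE is approximate where a group lies near 0 counts. A count of 0 was taken to allow up to 3 counts, which is 0.113 to 0.144 CPM.

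Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15714 genes; TMM scaling; quasi-likelihood F test, two-sided; 1 fit over the 9 libraries with a mean per group). The 3 comparisons were MyoD against MEF, F/R/C against MEF and F/R/C against MyoD. P-values were adjusted within each comparison by Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called. Transcripts were tested the same way on their estimated counts (44724 transcripts), and reported for Dmd and Mef2d. With 3 libraries against 3, an exact permutation test of a single value cannot give a two-sided p under 0.1.

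Before the data were examined, 28 gene lists (512 genes) were written down. They covered satellite cells and muscle progenitors, myogenic commitment and fusion, the sarcomere, the neuromuscular junction, excitation-contraction coupling, the dystrophin-associated complex, muscle energy metabolism, fibroblast identity, TGF-beta response, Wnt/beta-catenin targets, cAMP/CREB targets, the cell cycle, cell cycle exit and senescence, Notch targets, interferon response, cytokines and chemokines, unfolded protein and stress response, cholesterol synthesis, and glycolysis and hypoxia. The others were markers of macrophages, endothelium, epithelium, neural and glial cells, adipocytes, cartilage and bone, smooth muscle and pericytes, heart, and pluripotency. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, and again with an estimated correlation, with p-values adjusted over the lists and comparisons. Member counts were given over all genes tested and adjusted over the list alone. Some genes belong to more than 1 list, such as Heyl among the progenitor genes and Notch targets.

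The genes named were chosen by a rule written before the data were examined. It took Myod1, Pax7, Myf5, Myog and Dmd. It also took, per comparison, the 8 largest rises and 8 largest falls among called genes with an average log2 CPM of at least 3 and no overlap between the libraries of the groups. For each list described, it took up to 4 members: the 3 of smallest adjusted p in the direction of most members and 1 in the other. Predicted genes and pseudogenes were left out of the second part. Of the genes it gave, those that illustrate each group were described.

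The replicate numbers were compared across groups by the correlation of each library's deviations from its group mean. Equal numbers in MEF and MyoD correlated at 0.632 to 0.729 and in MEF and F/R/C at 0.101 to 0.151. In MyoD and F/R/C they correlated at 0.0837, 0.119 and 0.164, above every pair of unequal numbers (at most 0.0447) but not all over 0.1, the limit taken for pairing. Values from a fit with the replicate number as a block are given beside results where they change a call or move a count by over 1.5 times. List counts that it moved by 1 or 2 genes are not all given. Alternatives to the choices above were planned: DESeq2 1.42.0, its size factors in edgeR, total counts as the only scaling, no filter beyond 1 count, an average CPM of at least 1, fits of 2 groups alone, counts scaled from TPM by transcript length, stricter thresholds, the block, and leaving out each library in turn. Another 3 were added after seeing the data. The fry test (limma) of the lists was run beside camera. Simulated counts with known changes were run through the same steps in each comparison: edgeR recovered 0% to 2% of genes changed 2-fold, 38% to 54% at 4-fold, 62% to 66% at 8-fold and 74% to 88% at 16-fold, with 6 to 9 false calls. DESeq2 recovered 10% to 14%, 68% to 72%, 80% to 84% and 90% to 94%, with 57 to 64 false calls. Each run changed 200 genes and drew the libraries independently, without differences shared by replicate numbers. These rates hold for that setting only, since many more genes were called in the F/R/C comparisons.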

Results

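Gene expression was measured by sequencing of polyadenylated RNA from mouse embryonic fibroblasts (MEFs) of the Dmdmdx genotype. This genotype carries a premature stop codon in Dmd, the gene of the muscle membrane-linking protein dystrophin, and is a model of Duchenne muscular dystrophy. The 9 libraries formed 3 groups of 3. These were MEFs without treatment, MEFs with ectopic MyoD (the transcription factor encoded by Myod1, which can start the skeletal muscle programme in other cells), and MEFs with MyoD together with small molecules given as F/R/C, letters that the labels do not spell out. The title of the series concerns myogenic progenitors made by direct reprogramming, so the comparisons ask how far MyoD, alone or with the small molecules, moved the fibroblasts' expression toward muscle. The libraries held 21112071 to 24291056 estimated counts each, so that 3 counts, the limit that a count of 0 allows, corresponded to 0.113 to 0.144 CPM (counts scaled to equal effective library sizes). Such floors cover counting error only. The labels do not say that the libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries.

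The F/R/C libraries stood apart from the others. The first dimension of a multidimensional scaling of the 500 genes with the largest pairwise differences held 66.1% of the variation and ran from MEF replicates 1 and 2 to the F/R/C libraries, with MEF replicate 3 (-0.98) between MyoD replicates 1 and 2 (-1.52 and -1.15) and MyoD replicate 3 (0.46). The second dimension held 11.5% and set MEF replicate 3 and MyoD replicate 3 apart from the others. MEF replicate 3 also carried more muscle transcripts than the other MEF libraries. The summed level of the 40 sarcomere genes examined was 275 and 230 CPM in MEF replicates 1 and 2, 1363 CPM in MEF replicate 3, 2249 to 6587 CPM in the MyoD libraries and 64340 to 93910 CPM in the F/R/C libraries. Of these 40 genes, 39 were highest in MEF replicate 3 among the MEF libraries, and 33 lay lower in MEF replicate 3 than in every MyoD library. The share of counts from mitochondrial genes was 0.913% ± 0.158 (SD, n = 3) in MEF, 1.18% ± 0.0372 in MyoD and 2.42% ± 0.790 in F/R/C libraries.

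**Figure D1:**
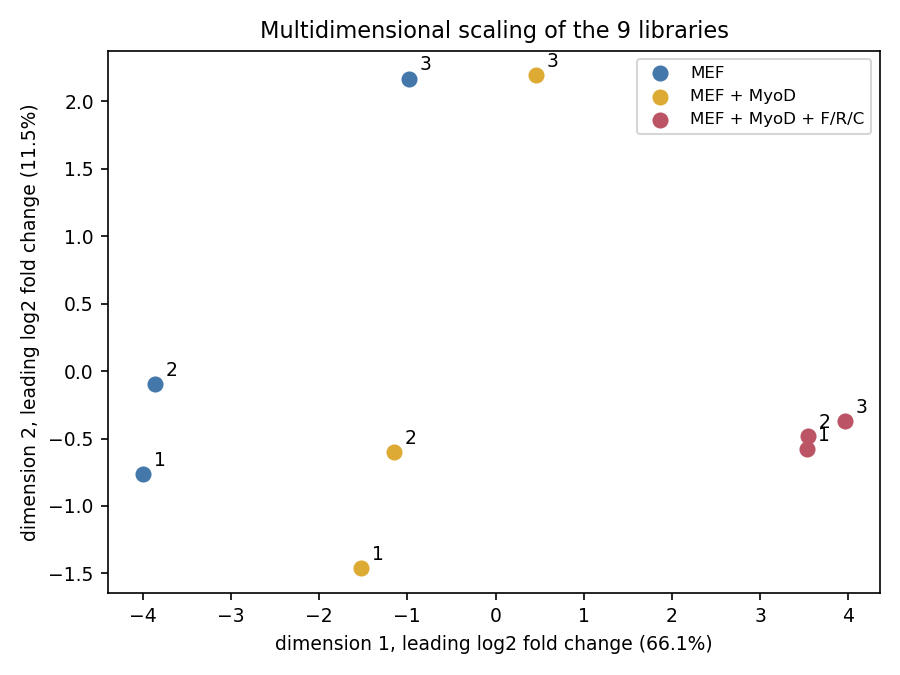
Multidimensional scaling of log2 CPM, with both axes as leading log2 fold changes and 1 point per library, coloured by group and marked with its replicate number. The F/R/C libraries lie together on the right, MEF replicates 1 and 2 on the left, and MEF replicate 3 and MyoD replicate 3 at the top.

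Myod1 itself (ENSMUSG00000009471, chromosome 7, 46376474 to 46379099, GRCm38) was measured first, since it was the factor introduced. Its estimated counts were 56, 10 and 130 in MEF replicates 1, 2 and 3, then 161, 239 and 394 in the MyoD libraries and 6412, 6163 and 6874 in the F/R/C libraries. The means were 3.00 ± 2.82 CPM (SD, n = 3), 11.7 ± 6.32 CPM and 293 ± 32.3 CPM. These counts do not separate transcripts of an introduced copy from those of the endogenous gene. The rise with F/R/C passed the test against MEF (log2 fold change 6.61 ± 0.89 SE, adjusted p = 0.00109) and against MyoD (4.65 ± 0.81, adjusted p = 0.00398), while the difference between MyoD and MEF libraries did not (1.97 ± 0.74, adjusted p = 0.886).

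Myog (ENSMUSG00000026459, chromosome 1, 134289989 to 134292548), the regulator of terminal muscle differentiation, averaged 6.42 ± 10.9 CPM in MEF, 35.1 ± 23.0 CPM in MyoD and 1178 ± 319 CPM in F/R/C libraries. It was higher with F/R/C than in MEF (log2 fold change 7.52 ± 1.85, adjusted p = 0.0130) and than in MyoD libraries (5.07 ± 1.65, adjusted p = 0.0427). The latter call ended without any 1 of the 6 libraries compared, with adjusted p from 0.0615 without MyoD replicate 3 to 0.129 without MyoD replicate 2. Between MyoD and MEF libraries Myog did not pass (2.45 ± 1.48, adjusted p = 1), but it did without MEF replicate 3 (adjusted p = 0.00338). Most of the MEF mean came from 1 library, with 413 counts in MEF replicate 3 against 2 and 3 counts in replicates 1 and 2. Pax7 (ENSMUSG00000028736, chromosome 4, 139737062 to 139833528), a marker of muscle satellite cells, had 0, 0 and 15 counts in MEF and 0, 0 and 3 counts in MyoD libraries, against 723, 374 and 174 counts in the F/R/C libraries (18.6 ± 11.1 CPM). Myf5 (ENSMUSG00000000435, chromosome 10, 107482908 to 107486134), another early myogenic regulator, had 0, 0 and 7 counts, 0, 0 and 2 counts, and 62, 83 and 91 counts (3.58 ± 0.900 CPM) in the same order. Both were higher with F/R/C than in MEF (adjusted p = 0.00874 for Pax7 and 0.0125 for Myf5) and than in MyoD libraries (0.00591 and 0.00821). In the libraries at 0, neither transcript was detectable at this depth.

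Dmd (ENSMUSG00000045103, chromosome X, 82948870 to 85206141) averaged 8.74 ± 8.40 CPM in MEF, 15.3 ± 9.84 CPM in MyoD and 18.4 ± 0.781 CPM in F/R/C libraries. No comparison passed the test: the log2 fold change was 0.81 ± 0.74 for MyoD against MEF (adjusted p = 1), 1.08 ± 0.74 for F/R/C against MEF (adjusted p = 0.282) and 0.27 ± 0.73 for F/R/C against MyoD (adjusted p = 0.805). Within the MEF group Dmd ranged from 2.46 to 18.3 CPM, and without MEF replicate 1, the highest, it passed for F/R/C against MEF (2.16 ± 0.68, adjusted p = 0.0442). At each replicate number Dmd was higher in the MyoD than in the MEF library (23.9 against 18.3, 4.57 against 2.46 and 17.6 against 5.49 CPM). The labels do not say that equal numbers are paired. None of the tested transcripts of Dmd passed the test in any comparison (edgeR on estimated counts per transcript), among them Dmd-203, which spans the gene, at 0.224 ± 0.188, 0.528 ± 0.555 and 1.13 ± 0.267 TPM, the deposited abundance scaled for transcript length, in the 3 groups. The log2 fold change of Dmd-203 in F/R/C against MEF libraries was 2.745 ± 1.16 (adjusted p = 0.178). Dmd-201, which covers only the end of the gene from 85048413, stood at 1.845 ± 2.32, 3.295 ± 3.24 and 1.10 ± 0.301 TPM. Summed over its transcripts, Dmd stood at 9.505, 1.512 and 3.71 TPM in MEF and 10.89, 2.187 and 4.57 TPM in MyoD libraries. The F/R/C libraries, at 4.289, 3.124 and 2.737 TPM, lay within the MEF range, so their higher mean CPM was not matched on this scale. These sums were not tested, and they join short transcripts with Dmd-203. Of Mef2d, a muscle transcription factor gene whose alternative transcripts were tested as well, Mef2d-201 rose from 31.0 ± 2.91 TPM in MEF and 36.0 ± 4.94 TPM in MyoD to 78.9 ± 27.1 TPM in F/R/C libraries (adjusted p = 0.00663 and 0.0146). Mef2d-202 was higher against MEF (3.50 ± 0.636 and 17.3 ± 10.5 TPM, adjusted p = 0.0419), a call that the replicate block ended (0.0724). Leaving out MEF replicate 1, 2 or 3, MyoD replicate 1, or F/R/C replicate 1 or 2 left 1 Mef2d transcript called against MEF. Against MyoD, 0 were called without MyoD replicate 1 or 2 and 2 without MyoD replicate 3.

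**Figure D2:**
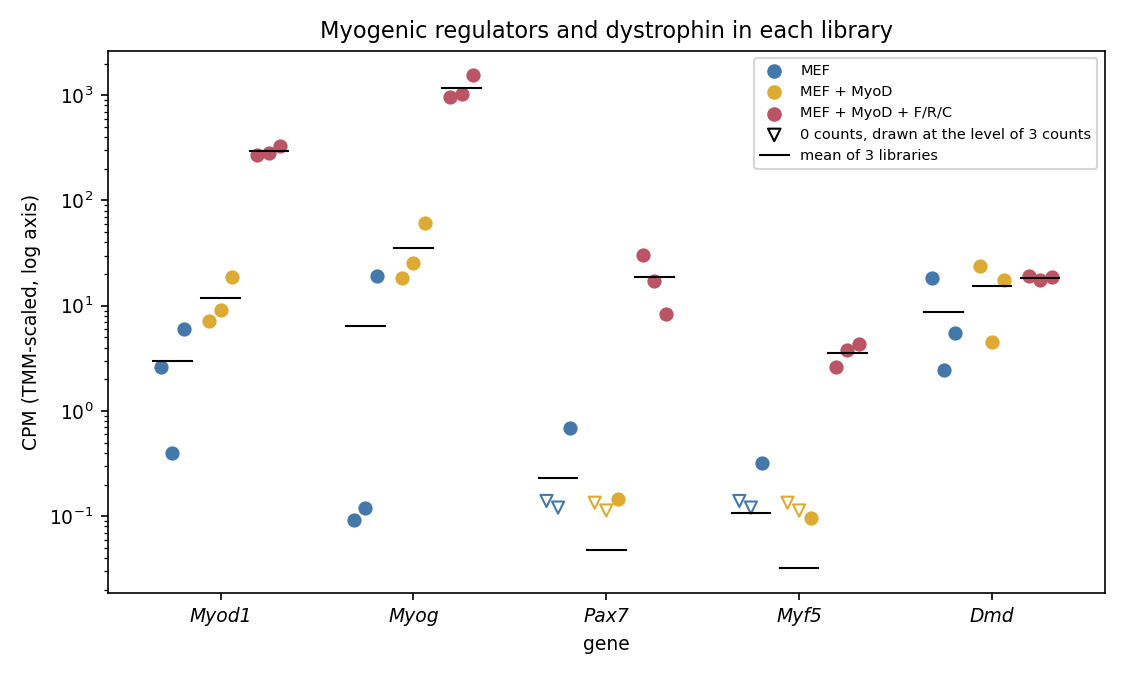
CPM (log axis) of Myod1, Myog, Pax7, Myf5 and Dmd, 1 point per library, coloured by group, with a line at the mean of 3 libraries. Open triangles mark libraries at 0 counts, drawn at the level of 3 counts and entered in the mean as 0; the F/R/C libraries lie above all others for the first 4 genes, while those of Dmd overlap with the other groups.

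MyoD alone was compared with untreated MEFs to see which genes changed without the small molecules. In MEFs with MyoD, genes of the contractile apparatus and of the neuromuscular junction stood higher as sets at the preset correlation (adjusted p = 0.208 for each with an estimated correlation), while no single gene passed the adjusted test. The smallest adjusted p, 0.0970, was shared by Sgca, a sarcoglycan of the muscle membrane (1.87 ± 0.564 CPM in MEF and 11.5 ± 2.01 CPM in MyoD libraries), Mb, the oxygen-binding protein myoglobin (0.236 ± 0.256 and 15.8 ± 4.10 CPM), and the fast myosin gene Myh2 (0.0769 ± 0.133 and 15.4 ± 5.64 CPM). Fibroblast and transforming growth factor beta (TGF-beta) response genes stood lower as sets at the preset correlation (adjusted p = 0.29 and 0.24 with an estimated correlation). The summed levels of both lists overlapped between the groups.

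All 40 sarcomere genes, which encode the proteins of the contractile unit, had a positive log2 fold change in MyoD against MEF libraries, with a median of 3.51. As a set they were higher (camera adjusted p = 1.51e-68, and adjusted p = 0.208 with an estimated correlation), with 0 members called over all genes and 22 when adjusted over the list alone. Tcap, a titin-binding protein, averaged 0.119 ± 0.142 CPM in MEF and 4.53 ± 0.955 CPM in MyoD libraries. MEF replicate 3, the highest MEF library for 39 of the 40 genes, lowers most of these changes. Without it the log2 fold change of Tcap went from 5.20 to 6.57 and that of Myh2 from 7.58 to 11.5. The MEF means of Tcap (0.119 CPM) and Myh2 (0.0769 CPM) lie within or under the level of 3 counts, 0.113 to 0.144 CPM. The sizes of these changes are therefore uncertain, most of all without MEF replicate 3. The 10 neuromuscular junction genes had a median of 3.01 (adjusted p = 1.68e-16, and 0.208 with an estimated correlation), with 8 members called when adjusted over the list alone. Among them Chrna1, a subunit of the acetylcholine receptor, stood at 3.07 ± 3.58 and 66.4 ± 43.7 CPM, and Ache, acetylcholinesterase, at 1.10 ± 1.04 and 7.36 ± 1.73 CPM. Their log2 fold changes went from 4.44 to 6.02 and from 2.75 to 3.865 without MEF replicate 3. The 21 genes of excitation-contraction coupling, the calcium release system of muscle, had a median of 2.71 (adjusted p = 8.42e-28, and 0.208 with an estimated correlation; 12 adjusted over the list alone). The 18 genes of muscle energy metabolism had a median of 2.74 (3.71e-20, and 0.208 with an estimated correlation; 11 adjusted over the list alone). The 25 genes of myogenic commitment and fusion had a median of 1.57 (2.21e-15, and 0.271 with an estimated correlation; 8 adjusted over the list alone). In this list Smyd1, a muscle methyltransferase, stood at 1.39 CPM in MEF and 31.5 CPM in MyoD libraries. Jsrp1 stood at 0.679 and 7.73 CPM. Most of both MEF means came from MEF replicate 3. In MEF replicates 1, 2 and 3, Smyd1 stood at 0, 0.121 and 4.06 CPM and Jsrp1 at 0.279, 0.282 and 1.48 CPM. Without MEF replicate 3 the log2 fold change was 8.84 for Smyd1 and 4.775 for Jsrp1. The size for Smyd1 is uncertain, since 0 and 0.121 CPM do not exceed the level of 3 counts. The 23 tested genes of satellite cells and muscle progenitors did not pass as a set (median 0.08, adjusted p = 0.439, but 0.0446 without the third library of both groups, left out after seeing the data), nor did the 21 genes of the dystrophin-associated complex (median -0.04, mean 0.20, adjusted p = 0.464).

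The 31 fibroblast identity genes had a median log2 fold change of -0.66 in MyoD against MEF libraries (camera adjusted p = 3.11e-06, and adjusted p = 0.29 with an estimated correlation), with 0 called over all genes and 0 adjusted over the list alone. Their summed level was 106200, 35520 and 36110 CPM in MEF replicates 1 to 3. In MyoD replicates 1 to 3 it was 49130, 17390 and 28780 CPM, so the groups overlapped for this list. The elastic fibre genes Mfap5 (23.3 CPM in MEF and 4.29 CPM in MyoD libraries) and Fbn1 (779 and 300.0 CPM) had some of its smallest p-values, and Ly6a was 1 of 7 members with a positive value, with 329 and 619 CPM. The 21 TGF-beta response genes had a median of -0.33 (adjusted p = 0.000649, and 0.24 with an estimated correlation), among them the collagen cross-linking enzyme Lox at 4749 ± 4555 and 1321 ± 1049 CPM. Their summed level was 21820, 11320 and 26520 CPM in MEF replicates 1 to 3. In MyoD replicates 1 to 3 it was 7778, 5760 and 24040 CPM, so MyoD replicate 3 lay within the MEF range. For both lists each MyoD library had a lower sum than the MEF library of equal number. The 20 cholesterol synthesis genes had a median of -0.27 (adjusted p = 1.75e-05, and 0.331 with an estimated correlation), a call that ended without MEF replicate 3 (adjusted p = 0.0532). All 22 interferon response genes had positive values, with a median of 1.00 (adjusted p = 2.66e-05, and 0.509 with an estimated correlation). The call ended without MyoD replicate 2 (adjusted p = 0.574). That library had the highest summed level of the list at 1549 CPM against 327 and 886 CPM in the other MyoD libraries and 334 to 764 CPM in MEF.

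By edgeR, 0 of the 15714 genes tested passed in MyoD against MEF libraries, with 732 at an unadjusted p under 0.05, of which 526 were higher and 206 lower. DESeq2 called 157 higher and 13 lower. The groups did not overlap for 7.52% of genes, against 10% by chance. That chance share assumes unpaired libraries, and pairing by replicate number lowers it, so 7.52% is no sign of less than chance. Without MEF replicate 3, 158 genes were higher and 3 lower, among them 36 of the 40 sarcomere genes, 13 of 21 genes of excitation-contraction coupling, 10 of 25 of commitment and fusion, 9 of 18 of energy metabolism and 8 of 10 of the neuromuscular junction. With the replicate number as a block, 13 genes were higher and 0 lower, among them Jsrp1, Stac3, Tcap, Sgca and Mb. The block fitted on the MEF and MyoD libraries alone, an alternative chosen after seeing the data, called 0 higher and 0 lower, with 1966 genes at an unadjusted p under 0.05. A fit of these groups without the block gave 454 such genes. So few libraries leave little to estimate the spread once group and number are fitted, so the 0 calls decide little.

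MyoD with F/R/C was compared with untreated MEFs as the full treatment. The F/R/C libraries carried a broad skeletal muscle expression programme: every one of the 40 sarcomere genes, 21 excitation-contraction coupling genes and 10 tested neuromuscular junction genes rose. Of the genes of fibroblast identity 13 of 31 fell, of the TGF-beta response 10 of 21 and of the interferon response 17 of 22; as sets they passed at the preset correlation but not with an estimated one (adjusted p = 0.331, 0.24 and 0.571). Penk, a neuropeptide precursor, had the largest fall of the named genes, from 3207 ± 2696 CPM in MEF to 7.29 ± 5.10 CPM (adjusted p = 0.00689). In all, 3067 genes were higher and 2849 lower, which is 37.6% of those tested (2392 and 2172 at an absolute log2 fold change of at least 1). The groups did not overlap for 53.2% of genes, against 10% by chance.

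The sarcomere genes had a median log2 fold change of 7.70 in F/R/C against MEF libraries, with 40 of 40 higher over all genes and 40 adjusted over the list alone (camera adjusted p = 5.76e-20, and adjusted p = 0.331 with an estimated correlation). Myoz1, a Z-disc gene, reached 223 CPM from 0.675 CPM in MEF (adjusted p = 0.00148). Tpm2, a tropomyosin present in both cell states, rose by less (log2 fold change 3.72 ± 0.45, adjusted p = 0.000735). Levels of single myosin heavy chain genes are uncertain, since their coding sequences are similar and reads were divided among them by estimation. All 10 neuromuscular junction genes rose, and 10 adjusted over the list alone (median 7.19; adjusted p = 5.24e-07, and 0.29 with an estimated correlation), as with Ache (100.1 ± 24.7 CPM, log2 fold change 6.52 ± 0.71, adjusted p = 0.000517) and Dok7, an activator of the receptor kinase of the junction (74.6 ± 13.5 CPM, 7.13 ± 1.02, 0.00136). All 21 excitation-contraction coupling genes rose, and 21 adjusted over the list alone (median 7.52; 6.65e-12, and 0.29 with an estimated correlation). Their smallest p belonged to Cacnb1, a subunit of the muscle calcium channel (17.2 ± 3.44 to 212 ± 21.4 CPM, adjusted p = 0.000210), and next came Stac3, a partner of that channel (0.974 to 101 CPM, 0.000322). Pvalb, a calcium-binding protein of fast muscle fibres in the same list, reached 79.5 CPM from 0.215 CPM (0.00122). Of 18 energy metabolism genes, 15 rose and none fell, and 15 adjusted over the list alone (median 6.82; 2.25e-08, and 0.29 with an estimated correlation). They included Pfkm, the muscle phosphofructokinase (64.4 ± 5.32 to 480 ± 77.8 CPM, adjusted p = 0.000178), and Pygm, the muscle glycogen phosphorylase (6.54 to 619 CPM, 0.000771). MEF replicate 3 and its muscle transcripts entered the MEF side of all these comparisons.

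Of 25 commitment and fusion genes, 19 rose in F/R/C against MEF libraries and 1 fell, with 20 and 1 adjusted over the list alone (median 6.65; camera adjusted p = 6.36e-09, and adjusted p = 0.331 with an estimated correlation). Mef2c, a partner of the myogenic factors, rose from 37.6 ± 18.5 to 1050 ± 67.7 CPM (adjusted p = 0.000568), and Bin1, which shapes the T-tubule membrane, from 93.7 to 1248 CPM (0.000265). The member that fell was Nfix, known for its part in the switch from embryonic to fetal muscle, from 664 ± 225 to 62.0 ± 27.0 CPM (0.00142). Of 23 progenitor genes, 10 rose and 4 fell, and 10 and 4 adjusted over the list alone (median 2.15; adjusted p = 0.012, and 0.331 with an estimated correlation). Fgfr4, a growth factor receptor of muscle progenitors, rose from 0.781 to 88.3 ± 11.7 CPM (adjusted p = 0.00252), while Vcam1, an adhesion molecule carried by satellite cells and by fibroblasts, fell from 320 ± 78.9 to 33.7 ± 15.7 CPM (0.000782). The number that fell was 2 without F/R/C replicate 3. Of 21 genes of the dystrophin-associated complex, 6 rose and 5 fell, the same adjusted over the list alone, and the set did not pass (median 0.20, adjusted p = 0.265). The sarcoglycan gene Sgca (log2 fold change 5.06 ± 0.32, adjusted p = 0.000177) and the dystrobrevin gene Dtna (4.88 ± 0.50, 0.000424) rose. Sgce, a widely expressed sarcoglycan, fell (-1.36 ± 0.28, 0.00607). The number that fell was 2 without any 1 F/R/C library.

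Of 31 fibroblast identity genes, 13 fell and 1 rose in F/R/C against MEF libraries, the same adjusted over the list alone (median -1.75; camera adjusted p = 0.00026, and adjusted p = 0.331 with an estimated correlation). Fstl1, a secreted glycoprotein, fell from 2252 to 397 CPM (adjusted p = 0.00231), Ly6a, a surface antigen of mesenchymal and other stem cells, from 329 to 40.9 CPM (0.000887), and Mfap5 from 23.3 to 0.969 CPM (0.00291). The member that rose was the transcriptional repressor gene Zeb2 (0.71 ± 0.23, 0.0377), and it was not called without MEF replicate 1 or 2, MyoD replicate 1 or 2, or F/R/C replicate 1 or 2 (adjusted p from 0.0525 to 0.144). Of 21 TGF-beta response genes, 10 fell and none rose, with 10 adjusted over the list alone (median -1.85; adjusted p = 0.000385, and 0.24 with an estimated correlation). Ltbp2 fell from 942 ± 313 to 41.9 ± 18.5 CPM (adjusted p = 0.000360), Lox from 4749 to 135 CPM (0.00352), and Bambi, a pseudoreceptor of the TGF-beta pathway, from 30.3 to 3.62 CPM (0.000847). Of 22 interferon response genes, 17 fell and none rose, with 18 adjusted over the list alone (median -2.82; adjusted p = 0.00017, and 0.571 with an estimated correlation), a number that was 8 without F/R/C replicate 3. Of 20 cholesterol synthesis genes, 10 fell and none rose, with 12 adjusted over the list alone (median -0.61; 0.00254, and 0.46 with an estimated correlation), a number that was 4 without F/R/C replicate 2. Fdft1, squalene synthase, fell from 92.6 to 42.6 CPM (0.00147).

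Of the 19 genes tested on the glycolysis and hypoxia list (18 symbols, as Aldoa has 2 gene identifiers, of which 1 was called), 12 rose and none fell in F/R/C against MEF libraries, with 12 adjusted over the list alone (median 1.39; camera adjusted p = 2.19e-06, and adjusted p = 0.271 with an estimated correlation). Egln3, an oxygen-sensing hydroxylase, rose from 3.85 ± 2.41 to 279 ± 42.6 CPM (adjusted p = 0.000360), and Bnip3, a mitophagy receptor, from 44.5 to 232 CPM (0.000227). Of 10 genes tested on the Notch target list 4 rose and none fell, with 4 adjusted over the list alone (median 1.39; adjusted p = 0.031, and 0.331 with an estimated correlation). Those that rose included Heyl (0.185 to 32.5 CPM) and Dll1 (1.25 to 26.6 CPM), which encodes a Notch ligand. Hes1 stood at 22.8 CPM in MEF and 32.1 CPM in F/R/C libraries, and Nrarp at 1.09 and 1.86 CPM. The call of the set ended without MEF replicate 1 (0.0503) or F/R/C replicate 1 (0.0792). Of 16 Wnt/beta-catenin target genes 4 rose and 2 fell, as when adjusted over the list alone (adjusted p = 0.147), with 8 and 2 in the fit with the replicate block. Of 17 cAMP/CREB target genes 2 rose and none fell, as when adjusted over the list alone (adjusted p = 0.451), with 4 and 3 in the block fit. Of 14 genes of cell cycle exit and senescence 4 rose and 2 fell, as when adjusted over the list alone (adjusted p = 0.506). Of 30 cell cycle genes 1 rose and 3 fell, with 1 and 2 adjusted over the list alone (adjusted p = 0.912). Of 15 cytokine and chemokine genes none rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.302). Of 16 genes of the unfolded protein and stress response 2 rose and 3 fell, with 1 and 2 adjusted over the list alone (adjusted p = 0.581). Of the 29 list counts between 1 and 5 in this comparison, 17 moved by over 1.5 times without some 1 library.

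F/R/C libraries were compared with MyoD libraries to see what differed when the small molecules were given with MyoD. Myod1 itself was higher with F/R/C (293 against 11.7 CPM). Differences that follow its level therefore cannot be told apart here from other effects of the small molecules. With F/R/C, 9 of 23 progenitor genes, 23 of 40 sarcomere genes and 11 of 19 genes of glycolysis and hypoxia rose, and 19 of 22 interferon response genes fell. These sets passed at the preset correlation but not with an estimated one (adjusted p = 0.331, 0.331, 0.271 and 0.46). Heyl, a Notch target expressed in satellite cells, stood at 0.213 ± 0.235 CPM in MyoD and 32.5 ± 8.60 CPM in F/R/C libraries (adjusted p = 0.00359). Col10a1, the collagen of hypertrophic cartilage, fell from 395 ± 440 to 1.65 ± 2.06 CPM (adjusted p = 0.00756). In all, 2796 genes were higher and 2531 lower, which is 33.9% of those tested (2146 and 1922 at an absolute log2 fold change of at least 1). The groups did not overlap for 49.8% of genes, against 10% by chance. Scaled by total counts only, 2295 were higher and 3119 lower, so that 42.4% of calls were higher against 52.5%, and the median log2 fold change of genes with a mean of at least 10 counts was -0.21 against -0.03. Without MyoD replicate 2 the number higher was 1778.

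Of 23 progenitor genes, 9 rose and 3 fell in F/R/C against MyoD libraries, with 10 and 4 adjusted over the list alone (median 1.53; camera adjusted p = 0.0124, and adjusted p = 0.331 with an estimated correlation). Eya4, a transcriptional cofactor of muscle progenitors, rose from 13.9 to 102 CPM (adjusted p = 0.00228), and Fgfr4 from 0.622 to 88.3 CPM (0.00297). Of 10 Notch target genes 4 rose and none fell, as when adjusted over the list alone, and the set did not pass (median 1.24, adjusted p = 0.0849). The Notch ligand gene Dll1 rose from 1.14 to 26.6 CPM (0.00330). Other members, such as Hes1 (36.3 CPM in MyoD and 32.1 CPM in F/R/C libraries) and Nrarp (2.20 and 1.86 CPM), did not rise. The Notch set passed without MyoD replicate 2 (0.0355) or F/R/C replicate 2 (0.0449). Without MyoD replicate 2 the number of Notch genes that rose was 2, and 1 progenitor gene fell without MyoD replicate 1, F/R/C replicate 2 or F/R/C replicate 3. Of 25 commitment and fusion genes, 18 rose and 1 fell, with 20 and 2 adjusted over the list alone (median 3.55; adjusted p = 9.87e-09, and 0.331 with an estimated correlation). Bin1 (log2 fold change 3.00 ± 0.31, adjusted p = 0.000674) and Mef2c (3.38 ± 0.50, 0.00221) rose and Nfix fell (-3.00 ± 0.48, 0.00299).

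Of the 40 sarcomere genes, 23 rose and none fell in F/R/C against MyoD libraries, with 36 adjusted over the list alone (median 4.06; camera adjusted p = 1.9e-16, and adjusted p = 0.331 with an estimated correlation). The number was 7 without MyoD replicate 2, 38 without MEF replicate 3, whose spread entered the same fit, and 37 with the replicate block. Tpm2 rose from 388 ± 188 to 3458 ± 1141 CPM (adjusted p = 0.00176), and Cmya5, a Z-disc and costamere protein, from 19.0 to 157 CPM (0.00199). The 10 neuromuscular junction genes all rose, and 10 adjusted over the list alone (median 3.71; adjusted p = 1.33e-06, and 0.29 with an estimated correlation), but 3 did without MyoD replicate 2. Lrp4, the receptor for nerve-derived agrin, rose to 82.5 ± 35.4 CPM with F/R/C (log2 fold change 1.78 ± 0.32, 0.00480). Of 21 excitation-contraction coupling genes 13 rose and none fell, with 21 adjusted over the list alone (median 3.59; 4.54e-11, and 0.29 with an estimated correlation), 7 without MyoD replicate 2 and 21 with the block. Jph1, which joins the T-tubule to the sarcoplasmic reticulum, rose from 17.8 to 177 CPM (0.00276). Of 18 energy metabolism genes 13 rose and none fell, as when adjusted over the list alone (median 3.80; 3.52e-07, and 0.29 with an estimated correlation). Slc2a4, the insulin-responsive glucose transporter, rose from 3.76 to 58.9 CPM (0.00429). Of 21 dystrophin-associated complex genes 7 rose and 1 fell, with 7 and 4 adjusted over the list alone and 7 and 5 with the block (median 0.41, adjusted p = 0.203).

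Of 22 interferon response genes, 19 fell and none rose in F/R/C against MyoD libraries, with 21 adjusted over the list alone (median -3.56; camera adjusted p = 1.11e-06, and adjusted p = 0.46 with an estimated correlation). Ifit3, an antiviral effector, fell from 50.6 ± 49.3 to 1.72 ± 0.434 CPM (adjusted p = 0.00195), while Ifit2 stood at 16.1 and 19.0 CPM (0.666). Of 21 TGF-beta response genes 9 fell and none rose, as when adjusted over the list alone (median -0.99; adjusted p = 0.00502, and 0.271 with an estimated correlation), a number that was 4 without F/R/C replicate 3. Ltbp2 fell by 4.10 ± 0.42 on the log2 scale (0.000665). Of 31 fibroblast identity genes 9 fell and 1 rose, with 8 and 1 adjusted over the list alone (median -0.83; adjusted p = 0.0275, and 0.509 with an estimated correlation). This call ended with total counts only (0.0513), without MyoD replicate 1 (0.136) and without F/R/C replicate 3 (0.0897). S100a4, a calcium-binding protein of fibroblasts, fell from 493 to 57.8 CPM (0.00217). Of 19 glycolysis and hypoxia genes 11 rose and none fell, with 12 adjusted over the list alone (median 1.37; 7.63e-07, and 0.271 with an estimated correlation). Bnip3 rose from 37.2 to 232 CPM (0.000286) and Tpi1, triosephosphate isomerase, from 347 to 1549 CPM (0.000708). The mitochondrial share of counts was higher in the same libraries (2.42% against 1.18%).

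Among the other lists in F/R/C against MyoD libraries, cell cycle exit and senescence had 4 genes up and 3 down of 14, with 5 and 3 adjusted over the list alone (adjusted p = 0.521). Cdkn1c, an inhibitor of cyclin-dependent kinases, rose from 16.3 ± 7.26 to 1112 ± 210 CPM (adjusted p = 0.000703), and Cdkn2b, another inhibitor of these kinases, fell from 109 to 42.6 CPM (0.00282). Of 30 cell cycle genes 1 rose and 3 fell, with 0 and 2 adjusted over the list alone (adjusted p = 0.706). E2f1, an activator of S phase genes, fell from 50.7 to 19.8 CPM (0.00145). Of 16 Wnt/beta-catenin targets 3 rose and 2 fell, as when adjusted over the list alone (adjusted p = 0.412). Of 17 cAMP/CREB targets 3 rose and none fell, as when adjusted over the list alone (0.462), with 5 and 1 in the block fit. Sik1, a kinase gene induced by cAMP, rose from 44.6 to 406 CPM (0.00112). Of 20 cholesterol synthesis genes 2 fell and none rose, as when adjusted over the list alone (0.0719, and from 0.0261 to 0.0449 without MEF replicate 2 or 3, MyoD replicate 2 or F/R/C replicate 2). The cholesterol set also passed with total counts only (0.028), no low-count filter (0.0297) and a fit of these groups alone (0.0392). Of 15 cytokine and chemokine genes 2 fell and none rose, as when adjusted over the list alone (0.43). Of 16 stress response genes 1 rose and 5 fell, as when adjusted over the list alone (0.43), with 2 and 6 in the block fit. Of the 30 list counts between 1 and 5 in this comparison, 22 moved by over 1.5 times without some 1 library.

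**Figure D3:**
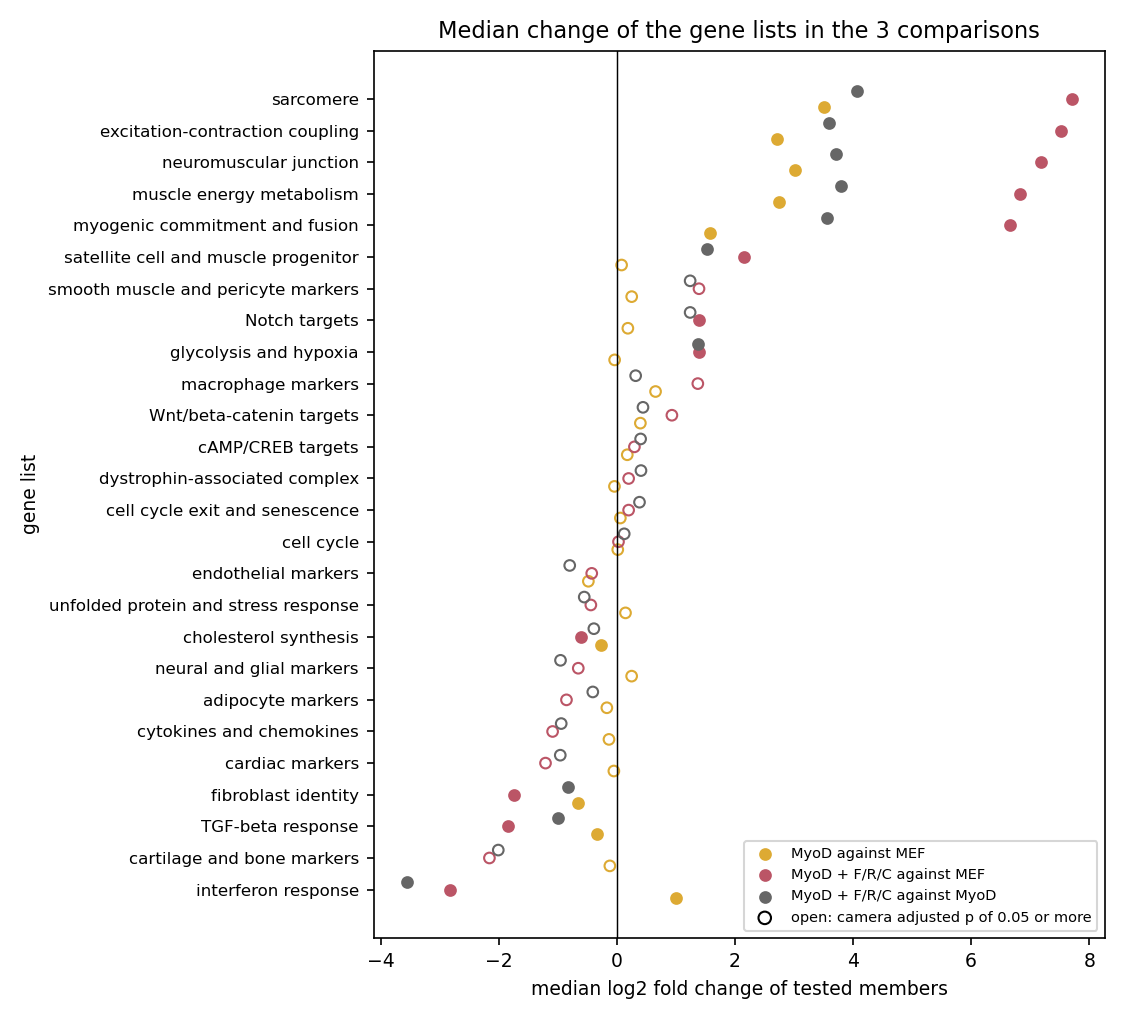
Median log2 fold change of the tested members of each gene list (horizontal axis) in the 3 comparisons, with filled points for a camera adjusted p under 0.05 at the preset correlation of 0.01; with an estimated correlation none passed. The 5 lists of differentiated muscle lie on the right in each comparison, and the interferon list lies at 1.00, -2.82 and -3.56, while medians of the dystrophin-associated, glycolysis and cardiac lists (MyoD against MEF) and of the cell cycle list (F/R/C against either group) change sign with the scaling.

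Markers of other cell types were tested as lists as well, and none of these sets passed in any comparison at the preset correlation. Of 7 tested macrophage markers, 3 were higher and none lower in F/R/C against MEF (adjusted p = 0.112) and 2 in F/R/C against MyoD libraries (0.222), among them Fcer1g, a subunit of immune receptors, at 0.254 CPM in MEF, 1.22 CPM in MyoD and 14.2 CPM in F/R/C libraries. Endothelial markers gave 0 higher and 2 lower of 6 against MEF (0.493) and 1 and 1 against MyoD (0.696). Cartilage and bone markers gave 1 higher and 3 lower of 10 against MEF (0.281) and 0 and 5 against MyoD (0.234). Smooth muscle and pericyte markers gave 3 higher and 2 lower of 9 in both comparisons (0.396 and 0.372), adipocyte markers 2 and 2 of 12 (0.912) and 3 and 2 (0.787), neural and glial markers 1 and 2 of 9 in both (0.912 and 0.862), and cardiac markers 2 and 1 of 8 in both (0.912). Of epithelial and pluripotency markers fewer than 5 were tested, so they had no set test: 3 of 4 and 1 of 3 were higher against MEF, and 2 of 4 and 1 of 3 against MyoD. Adjusted over the list alone, these counts differed only for neural markers (1 lower against MEF), cartilage markers (1 higher and 6 lower against MyoD), cardiac markers (2 lower against MyoD), epithelial markers (3 higher against MyoD) and pluripotency markers (1 lower against MyoD). In MyoD against MEF libraries edgeR called none of these markers, nor any member of the lists not described above, and adjusted over the list alone it called 1 macrophage, 1 adipocyte and 1 pluripotency marker and 2 genes of the dystrophin-associated complex. With the replicate block, the macrophage (adjusted p = 0.0373 against 0.051) and endothelial sets (0.0359 against 0.0673) passed in MyoD against MEF, and the cartilage and bone set (0.043 against 0.281) in F/R/C against MEF libraries, where it also passed without MEF replicate 3 (0.0449). Without the third library of both MEF and MyoD, the endothelial set passed in MyoD against MEF (0.0259). The cartilage and bone set then passed in F/R/C against MEF (0.0183) and against MyoD libraries (0.0341), and the Notch call in F/R/C against MEF ended (0.0621).

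In MyoD against MEF libraries, the sets without a call and not named so far had adjusted p of 0.0509 (Wnt/beta-catenin targets, median 0.40), 0.888 (cAMP/CREB targets, 0.18), 0.731 (cell cycle, 0.01), 0.731 (cell cycle exit and senescence, 0.06), 0.203 (Notch targets, 0.19), 0.229 (cytokines and chemokines, -0.14), 0.462 (stress response, 0.15) and 0.833 (glycolysis and hypoxia, -0.04). For the marker lists they were 0.102 (neural and glial), 0.49 (adipocyte), 0.932 (cartilage and bone), 0.199 (smooth muscle and pericyte) and 0.49 (cardiac). The median, the mean and the set test differed in sign for some sets that did not pass. In MyoD against MEF these were the dystrophin-associated complex, the cell cycle, cell cycle exit, and glycolysis lists. Some sets passed without 1 library, among them the cell cycle set, up without MEF replicate 1 (0.000226) and down without MEF replicate 3 (0.0234). The others were cytokines and chemokines (0.00639 without MEF replicate 1 and 0.0368 without MyoD replicate 2), Wnt targets (0.0296 without MEF replicate 2, and 0.0392 in a fit of these groups alone), the stress response (0.0409 without MEF replicate 3), neural markers (0.0459 without MEF replicate 2 and 0.0449 without MyoD replicate 1) and cartilage markers (0.0249 without MEF replicate 3). The macrophage set passed without MEF replicate 1, MyoD replicate 2, or F/R/C replicate 1 or 3 (0.0134 to 0.0485), and the endothelial set without F/R/C replicate 2 (0.0397) and with total counts only (0.0279). In F/R/C against MEF the signs differed for the cell cycle, neural and cardiac lists, and in F/R/C against MyoD the Wnt, cell cycle, adipocyte and cardiac lists.

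**Figure D4:**
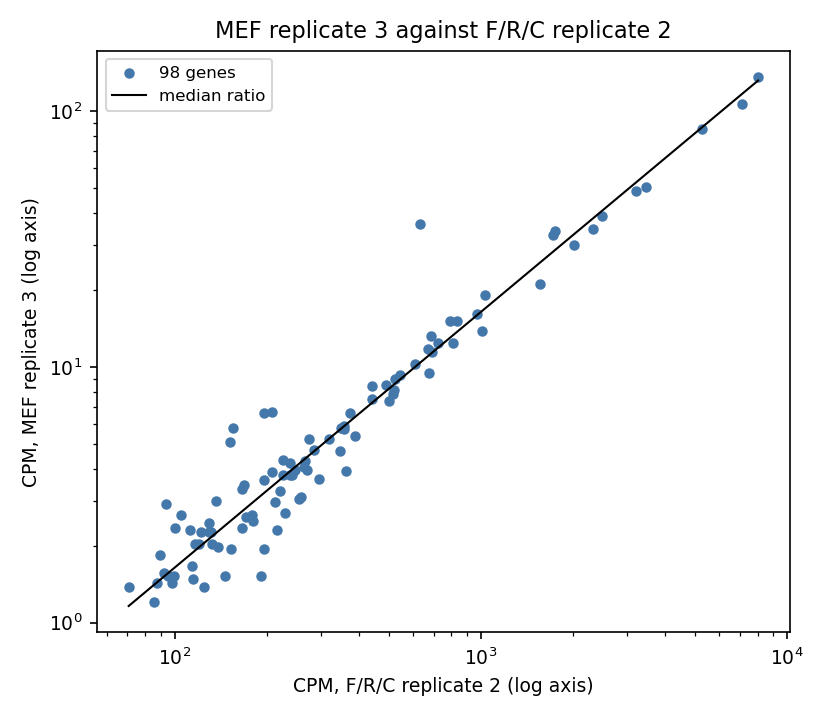
CPM in MEF replicate 3 (vertical log axis) against CPM in F/R/C replicate 2 (horizontal log axis) for 98 genes with a mean of at least 100 CPM in F/R/C libraries and under 1 CPM in MEF replicates 1 and 2, with a line at their median ratio of 1.64%. The points follow the line with a median absolute deviation of 0.24 on the log2 scale.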

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

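The tests of MEF replicate 3 by ratios and by its label, those of the missing calls between MyoD and MEF, and the counts of other splits were chosen after the results they concern were seen; the regression of MEF replicate 3 on the F/R/C libraries was written before its result.

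Of the counts of the F/R/C libraries, 0.470% (mean of 3 libraries) fell on transcripts absent from the annotation used, against 0.204% in MEF and 0.218% in MyoD libraries. These transcripts enter no comparison of genes, and their share was higher than in the control libraries.

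MEF replicate 3 carried muscle transcripts at levels above MEF replicates 1 and 2. Of 61 genes high in MyoD replicates 1 and 2 and near 0 in MEF replicates 1 and 2, 86.9% lay lower in MEF replicate 3 than in every MyoD library. MEF replicate 3 was thus unlike these MyoD libraries. The test cannot exclude a mislabelled or swapped MyoD library with weaker muscle expression, since the genes were chosen as high in MyoD libraries. Myog had 413 counts in MEF replicate 3 and 411 in MyoD replicate 1, and Myod1 130 and 161. Over the 98 genes described next, MEF replicate 3 held a median of 52.3% of the level of MyoD replicate 1. Over 98 genes abundant with F/R/C, MEF replicate 3 held 1.64% of the level of F/R/C replicate 2, with a median absolute deviation of the log2 ratio of 0.239, against 0.416 and 0.516 for F/R/C replicates 1 and 3 and 0.79 to 1.12 for the MyoD libraries; this may reflect reads or RNA carried over from an F/R/C library. At that ratio MEF replicate 3 held more counts than a plain copy gives of Pax7 (15 against 6.07, or 11.3 from F/R/C replicate 1). The same held for Myf5 (7 against 1.35), Myod1 (130 against 100) and Myog (413 against 366). One-sided Poisson p-values against F/R/C replicate 2 were 0.00158, 5e-04, 0.00236 and 0.00876 in that order, from counting error only. These excesses do not decide the source. Pax7 and Myf5 rest on few counts, and MEF replicates 1 and 2 held 56 and 10 counts of Myod1. The ratio itself varied between genes, from 0.795% to 5.74% over the 98 (SD 0.399 on log2). Muscle cells in the third MEF culture cannot be told apart from such carry-over, since the regression coefficient of F/R/C replicate 2 was 0.712 ± 0.118 SE and its interval of 2 SE reached below 0.5. A source shared by the third libraries of MEF and MyoD stays open as well, untested: over the same 61 genes MyoD replicate 3 stood at a median of 2.79 times the mean of MyoD replicates 1 and 2, and the deviations of MEF and MyoD replicate 3 from their group means correlated across genes at 0.729 (0.655 and 0.632 for the other numbers), while beside muscle cells in the culture no biological explanation was tested, since the design names no other.

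By edgeR no gene was called between MyoD and MEF libraries, with 732 at an unadjusted p under 0.05 and 170 called by DESeq2. The muscle transcripts of MEF replicate 3 may widen the spread: without it 161 genes were called, against 0 without MEF replicate 1 or 2. Differences shared by the libraries of equal number may widen it too, since 13 genes were called with the replicate block. Those 13 calls rest on a fit that holds the F/R/C libraries. The block on MEF and MyoD alone called 0, with 1966 genes at an unadjusted p under 0.05. A fit of these groups without the block gave 454 such genes. With group and number both fitted, so few libraries leave little to estimate the spread. The 0 calls therefore do not argue against shared differences. Both explanations remain open and neither excludes the other. The treatment itself, a biological difference that the design names, stays open as to single genes.

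The 6 libraries of each comparison can be split in 10 ways, which is too few for a share under 0.05. The real split of MyoD and MEF called 0 genes and the highest of the others 0, so that 10 of 10 splits were as large. The real splits called 5916 genes for F/R/C against MEF and 5327 for F/R/C against MyoD, and the highest of the others 0 in each, so that 1 of 10 splits was as large.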

How the results depend on the processing

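Leaving out the third library of both MEF and MyoD, the block on MEF and MyoD alone, and the block with an estimated correlation were chosen after seeing the data; the other alternatives were planned. The cause of a change was not tested unless stated.

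For MyoD against MEF, 0 genes higher and 0 lower became 157 and 13 with DESeq2, 10 and 1 with no low-count filter, 13 and 0 with the replicate block, 198 and 1 without the third library of both groups, and 0 to 158 and 0 to 3 without single libraries (158 and 3 without MEF replicate 3). The block on MEF and MyoD alone gave 0 and 0, with 1966 genes at an unadjusted p under 0.05, against 454 in a fit of these groups without the block. For F/R/C against MEF, 3067 and 2849 became 1775 and 1360 at an adjusted p under 0.01, by construction, and ranged from 2168 to 3260 and 2065 to 3102 without single libraries. For F/R/C against MyoD, 2796 and 2531 became 1282 and 1094 at that threshold, and ranged from 1778 to 2756 and 1744 to 2819. The block gave 3348 and 2986, for groups whose equal numbers correlated weakly (0.0837 to 0.164). DESeq2 gave 3716 and 3203, and 3392 and 2971.

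Lists called were 9, 12 and 10 in the 3 comparisons, and 0, 0 and 0 with an estimated correlation, with or without the block. The block gave 11, 13 and 10 and fry 4, 16 and 13. Of the 31 calls, 30 or 31 were shared by each of the other alternatives for which camera was run. It was not run with DESeq2, the stricter thresholds or the block on MEF and MyoD alone. Mef2d transcripts called against MEF were 2, 1 with the block and 1 to 2 without single libraries; against MyoD they were 1, and 0 to 2.

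Of the core genes, Myog in MyoD against MEF (2.45) passed at 8.30 without MEF replicate 3 and at 7.65 without the third library of both groups, and ranged from 1.77 to 8.30 without single libraries. Myog in F/R/C against MyoD (5.07) no longer passed at 4.76 and 4.85 without MyoD replicates 1 and 2, 5.74 without MyoD replicate 3, and 5.20, 5.16 and 4.83 without F/R/C replicates 1, 2 and 3 (range 4.75 to 5.74). Dmd in F/R/C against MEF (1.08) passed at 2.16 without MEF replicate 1 (range 0.58 to 2.16). No called value reversed. Of the other named genes, the rise of Zeb2 against MEF alone ended under some alternatives, and in MyoD against MEF libraries 9 passed with DESeq2, 5 with the block, 4 with no low-count filter, 9 without MEF replicate 3 and 9 without the third library of both groups.

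At this depth 3 counts were 0.113 to 0.144 CPM, which limits Pax7 and Myf5 in the libraries at 0. Without MEF replicate 3, sizes of change are uncertain for genes near 0 in MEF replicates 1 and 2, such as Myh2, Smyd1 and Myog.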

Other observations

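The test of the imprinted list was written before its result, on genes not yet looked at.

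High levels of H19 and Igf2 in the F/R/C libraries (23422 and 14200 CPM, against 2999 and 1605 CPM in MyoD libraries) led to the hypothesis that imprinted growth genes rise together with F/R/C. Genes seen beforehand were left out: H19, Igf2, Cdkn1c and Rtl1, which were higher, Sgce, which was lower, and Dcn. The other 13 were higher as a set in F/R/C against MyoD libraries (camera p = 2.36e-05, and 0.0499 with an estimated correlation; median log2 fold change 2.93, 8 called higher and 0 lower). Meg3 stood at 378 and 2888 CPM, Dlk1 at 88.8 and 1833 CPM, and Peg3 at 74.2 and 847 CPM, while Igf2r (890 and 799 CPM) and Plagl1 (157 and 181 CPM) were not called. Against MEF the p was 0.000494, and 0.0936 with an estimated correlation, with 7 called higher. In MyoD against MEF libraries the set was lower (0.00672, and 0.173 with an estimated correlation) with 0 calls by edgeR. Of the 8 called, 4 (Meg3, Dlk1, Rian and Mirg) lie in the same cluster on chromosome 12 as Rtl1, which had been seen, so they are not independent of it. Whether the other called genes, such as Peg3 and Zim1, share clusters was not examined, so they may not be independent either. The set p of 2.36e-05 is consistent with a rise of several of these genes with F/R/C, and whether imprinting itself changed was not measured.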
